A study of Mus musculus with 6 samples.

How the data were processed

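Total RNA from the livers of 3 male mice was measured on 2 kinds of expression array, A and B, with 1 mouse in each of 3 groups defined by age and diet, per the labels. The deposited values were read as spot intensity on a linear scale in arbitrary units, because the values were positive, right-skewed and differed several-fold in median between arrays. What the authors did to make the deposited intensity values, including the label chemistry, scanner, background treatment and any scaling, was not given in the sources used here. Whether background had been removed stays unknown, so fold differences of dim spots may be too small or too large. Per array, 11 to 66 spots held a value of exactly 10, far more often than any other value, which were kept in the main setting and left out in an alternative.

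Probes were named through the platform annotation held by GEO. Of 16896 spots on both arrays, 9663 had 1 gene symbol, 436 had several and 6797 had none there. A spot with several symbols or none was not named. Of the named spots, 9641 were matched through the gene number to RefSeq gene names for the mouse assembly GRCm38.p6, and 0 symbols changed. No coordinates were used, since the arrays name no genome build. Of the columns of values, 0 were left without a mouse.

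Intensities were raised to a floor at the 5th percentile of each array, log2-transformed and quantile-normalized over the 3 arrays of a kind. A probe entered where its mean over the 3 mice lay above the 50th percentile of its array kind. A high value in 1 mouse could thus let a probe in. A gene took the median difference of its entering probes over both arrays, which gave 3865 genes. A gene was counted as higher or lower at a log2 difference of at least 1, which is 2-fold. The 3 comparisons were 174 against 17 days on the ad libitum diet, calorie restriction at 177 days against ad libitum at 174 days, and calorie restriction at 177 days against ad libitum at 17 days. With 1 mouse per group no test, p-value or standard error could be given, and every difference describes these mice only, without a replicate check.

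There were 38 gene lists for pathways, cell types and complexes. A list with at least 5 measured genes was described by the percentile of its median among 10000 random lists of the same size, matched on mean level in 10 bins, and called apart below the 2.5th or above the 97.5th percentile. Fewer than 5 genes were measured for 17 of the lists. The named genes were, per comparison, the 8 highest and 8 lowest; the 5 highest and 5 lowest among genes with at least 2 entering probes in the same direction, ranked by the smallest probe difference; up to 4 members of each list that stood apart; and Igf1, Igfbp1, Igfbp2, Afp, H19, Igf2, Cyp7a1, Pck1, Fasn, Scd1, Alb, Hspa5 and a further gene that is not reported here, where a probe entered. Igf1, H19, Igf2, Alb and Hspa5 had an entering probe. Other genes named as members of a list, and Csf1, were chosen after their values were seen. The lists, the rule for named genes, the main setting and most alternatives were fixed before the data were examined.

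The alternatives were median centring of each array, no scaling, loess of the difference on mean level with a span of 0.3, no filter or only the top 25% of probes by level, a floor at the 25th percentile, the brightest probe of a gene, a threshold of 1.5-fold, and each array kind alone. Chosen after the data were seen were leaving out spots of exactly 10, leaving out spots at least 1.5 log2 from both other mice in the 174-day mouse only or in the 17-day mouse only, and a correction for spot position. The position correction removed the median deviation of each of 16 blocks of 528 consecutive spots and of each place within a block. The spot layout was not given in the sources used here, and the block length was the divisor of the number of spots at whose distance the differences between mice correlated most. The procedure was tested on simulated data for the age comparison, with 100 genes planted at each size. There, 47.0% of 2-fold and 98.0% of 4-fold differences passed the threshold, as did 2.18% of 3665 unchanged genes. All probes of a gene got the same difference and all mice the same normal spread (SD 0.317 log2). Effects of spot position, misnamed probes and single spots far apart were left out, and the entering probes were those of the real data. Recovery in the real arrays may thus be lower. A list of 15 genes, shifted in the finished gene values to a median of 0.64 log2, reached the 100.0th percentile. A list without a shift (median 0.12) reached the 84.4th. With a single list of each kind, neither the rate of false calls nor the recovery of smaller shifts was measured. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.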

Results

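RNA from the livers of 3 male mice was hybridised to expression arrays, with 1 mouse in each group. A mouse fed ad libitum was killed at 17 days, per its label, and belonged to the 1st age group. The unit of that age rests on the label alone and was not checked by any other source used here. Another ad libitum mouse was killed at 174 days and a calorie-restricted mouse, kept on a reduced food intake, at 177 days, both in the 2nd age group. Each liver was measured on array A and on array B, which carry different sets of 8448 spots, so that 6 arrays were compared. Median spot intensity on array A was 364.3 in the 17-day mouse, 35.8 in the ad libitum 174-day mouse and 375 in the calorie-restricted mouse. On array B the medians were 402.5, 60.8 and 332.8, so the ad libitum 174-day mouse had the dimmest array of both kinds. Across the spots of array A, log2 intensities of the 17-day and the calorie-restricted mouse correlated with a Pearson r of 0.961, and those of the 174-day mouse with these at 0.928 and 0.905. On array B the same pairs gave 0.975, 0.964 and 0.936. No group had a replicate, so no difference has an error between animals, and the single mouse per group limits the precision of every value.

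**Figure D1:**
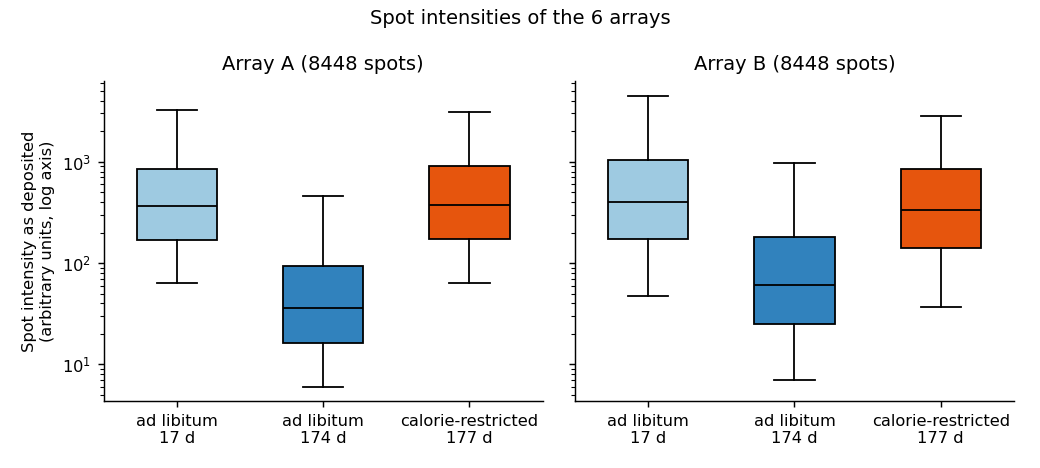
Spot intensity as deposited (arbitrary units, log axis) on array A and array B for each of the 3 mice. Lines mark the median, boxes the quartiles and whiskers the 5th and 95th percentiles of 8448 spots, and the ad libitum 174-day mouse has the lowest median on both arrays, 35.8 on A and 60.8 on B.

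The first comparison set the ad libitum mouse of 174 days against that of 17 days and asks how liver expression differed with age. The highest values in the older mouse belonged to Arhgap1, which encodes a GTPase-activating protein (5.23 log2 higher), Mrpl50, of the mitochondrial ribosome (4.52), Neto2 (4.16) and H2az1, the histone variant H2A.Z (4.02). Tns3, a focal adhesion protein (3.97), Lig1, a DNA ligase of replication and repair (3.93), Eif2a (3.71) and the ribosomal protein gene Rps14 (2.74) completed the 8 highest. The lowest values were those of Rsl1d1 (-5.17), Hsbp1, which binds heat shock factor (-4.68), Map1lc3b, an autophagosome protein (-2.60), and H3f3b, one of the genes of histone H3.3 (-1.73). Cyhr1 (-1.35), the proton pump subunit gene Atp6v0a1 (-1.24), the glutathione transferase Gstp1 (-1.20) and Cited4 (-1.19) followed. Among 3865 genes, 28 were at least 2-fold higher and 17 at least 2-fold lower in the 174-day mouse.

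Each of the 8 highest genes rested on a spot that stood apart in the 174-day mouse only, and 6 of the 8 had entering probes on array A alone. Of these, Tns3 and Lig1 also had a dimmer probe on array B that did not enter. The Arhgap1 spot read 283.4 in the 17-day mouse, 1548 in the 174-day mouse and 338.6 in the calorie-restricted mouse, although the 174-day array was about 10 times dimmer at its median. The array A probe of Mrpl50 differed by 8.94 log2 and its array B probe by 0.10. For H3f3b the 2 probes above the brightness filter differed by -3.22 and -0.25. Dimmer probes of the same names, which did not enter, lay from -0.05 to 0.80 for the 3 of H2az1, at 0.11 for Tns3, 0.16 for Lig1, 0.42 for Rps14, 0.77 for Rsl1d1 and 1.11 for Map1lc3b. With them, H2az1 was at 0.49, H3f3b at -0.10, Map1lc3b at -0.74 and Cyhr1 at -0.86, whereas Lig1 (2.045), Tns3, Rps14 and Rsl1d1 stayed at least 2-fold apart. The Rsl1d1 spot read exactly 10 in the 174-day mouse, a value shared by 57 spots of that array, against 2283 and 1882 in the other mice. Without the spots that stood apart only in the 174-day mouse, 12 genes were at least 2-fold higher and 16 lower.

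Genes with at least 2 entering probes in the same direction were ranked by their smaller probe difference. Rnf14, an E3 ubiquitin ligase gene, ranked first on the higher side, with entering probes at 1.32 and 3.66 log2. The probe at 3.66 stood apart in the 174-day mouse only, and a dimmer probe of Rnf14 was at -0.30. Next came Rpl27a (0.62), of the large ribosomal subunit, the helicase gene Dhx36 (0.55), Cdc14b (0.38) and Arih2 (0.39). Dimmer probes were at -1.40 for Cdc14b and 0.18 for Arih2. On the lower side were Uhrf1bp1l (-0.87), Rragc, a GTPase gene of amino acid sensing by mTORC1 (-0.91), Nynrin (-0.77), Cspp1 (-0.70) and Ccdc86 (-0.61). Only Rnf14 had every entering probe at least 2-fold apart in the age comparison.

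Antioxidant enzyme genes had higher values in the 174-day than in the 17-day mouse as a group. The median of 15 genes was 0.17 log2, at the 98.5th percentile of random lists of the same size and level, with 9 genes above 0, 6 below and none 2-fold apart. Sod1, the cytosolic superoxide dismutase, was 0.73 higher, the peroxiredoxin Prdx1 0.55, the heme oxygenase Hmox1 0.47 and the selenium carrier Selenop 0.46, whereas Txnrd1 was at -0.58 and Mt1 at -0.42. Hepatocyte secreted and identity genes had lower values, with a median of -0.30 over 6 genes at the 1.29th percentile, 5 below 0 and none 2-fold apart. They included the nuclear receptor Nr5a2 (-0.54), Serpina1e, an alpha-1-antitrypsin gene (-0.46), the corticosteroid-binding globulin Serpina6 (-0.31) and Alb, the albumin gene (-0.29), while Apoa1 was at 0.07. These were 2 of 21 lists with a percentile, where chance places 1.05. Neither direction was seen in the calorie-restricted mouse against the same 17-day mouse. There the antioxidant median was -0.09 (58.1st percentile) and the hepatocyte median 0.06 (84.8th percentile). Neither list stood apart after a correction for spot position (percentiles 92.9 and 12.3) or with each array centred on its median alone (94.1 and 4.92), and on array A alone the antioxidant median was -0.05. Alb itself was at 0.25 after the correction for position.

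Lipid synthesis genes lay near the upper end without standing apart. Fatty acid synthesis genes had a median of 0.21 over 9 genes (96.8th percentile), with the ATP citrate lyase Acly at 0.90 and the fatty acid elongase Elovl6 at 0.45, but the transcription factor Srebf1 at -0.67. Cholesterol synthesis genes had a median of 0.21 over 5 genes (94.6th percentile), from -0.11 for Sqle to 0.35 for Idi1. The 12 fetal and neonatal liver genes had a median of -0.04 (48.8th percentile) and none was 2-fold apart. Among these developmental genes, H19, an imprinted fetal RNA, was at -0.06 and Igf2, a fetal growth factor, at 0.13, while Cdkn1c, an imprinted inhibitor of the cell cycle, was at -0.71. A dimmer probe of Igf2 was at -0.75, and the gene was at -0.31 with it and at -0.10 after the correction for position. Over all 7 probes named for H19, including those below the brightness filter, the difference ran from -0.26 to 0.40. Cell cycle genes had a median of -0.07 over 31 genes (22.1st percentile), 12 above 0 and 19 below, and the 2 that were 2-fold higher, H2az1 and Lig1, rested on the spots described above. The proliferation marker Mki67 was at -0.66 and the mitotic kinase Cdk1 at -0.84, but the replication helicase subunit Mcm6 at 0.51 and the phosphatase Cdc25c at 0.45. After the correction for position the cell cycle median was 0.10 (98.9th percentile) and that of fatty acid synthesis 0.21 (99.1st percentile). Erythroid genes had a median of -0.08 over 8 genes (32.6th percentile), with the alpha globins Hba-a1 at -0.18 and Hba-a2 at 0.12. Over all 12 probes named for Hba-a1 the median was 0.17, from -0.28 to 0.49. Igf1, the main hepatic growth factor of the postnatal animal, was at -0.04, but at 0.34 after the correction for position. The chaperone Hspa5 was at 0.01, with entering probes at -0.15 and 0.17. A dimmer Hspa5 probe was at -0.85, and with it the gene was at -0.15.

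**Figure D2:**
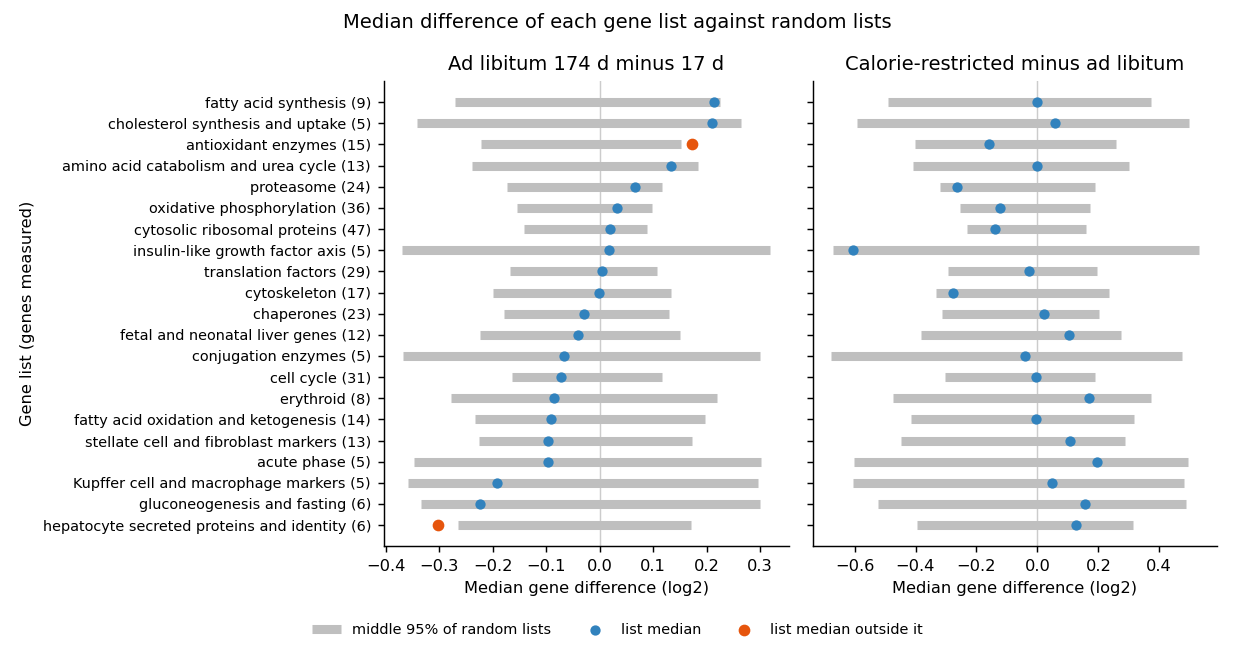
Median log2 difference of each gene list (points) with the middle 95% of medians of 10000 random lists matched in size and level (grey bars), for 174 d minus 17 d on the left and calorie-restricted minus ad libitum on the right. In the age comparison the antioxidant median (0.17) lies above and the hepatocyte median (-0.30) below its bar, and in the diet comparison every median lies inside.

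The second comparison set the calorie-restricted mouse of 177 days against the ad libitum mouse of 174 days and asks how liver expression differed with diet. Apart from Rsl1d1 (5.44), whose 174-day value was exactly 10, the highest genes in the calorie-restricted mouse were Rnmt, the mRNA cap methyltransferase (1.79 log2), Xbp1, a transcription factor of the unfolded protein response (1.71), and the cytochrome P450 gene Cyp2s1 (1.69). Oxsm, of mitochondrial fatty acid synthesis (1.68), Esyt1, which tethers the endoplasmic reticulum to the plasma membrane (1.63), the aminopeptidase Xpnpep1 (1.56) and Cdkn1c (1.55) followed. All from Rnmt to Cdkn1c were lower in the 174-day than in the 17-day mouse, from -0.97 (Xbp1) to -0.71 (Cdkn1c). Set against the 17-day mouse, the calorie-restricted mouse had them at 0.62 (Xpnpep1) to 0.93 (Cyp2s1), below 2-fold. In the diet comparison a dimmer Xpnpep1 probe was at -5.79, and with it the gene was at -2.11. Alb was 1.18 higher, but at -0.15 with median centring. The lowest were Arhgap1 (-5.02), Mrpl50 (-4.57), H2az1 (-4.45), Tns3 (-4.41), Neto2 (-4.23), Eif2a (-4.12), Lig1 (-4.04) and Bcap31 (-3.14), and each of these 8 rested on a spot that stood apart in the 174-day mouse only. The Mrpl50 probes were at -8.87 on array A and -0.27 on array B. Without the brightness filter H2az1 was at -0.56, Tns3 at -2.17 and Lig1 at -2.06. In all, 87 genes were at least 2-fold higher and 178 at least 2-fold lower in the calorie-restricted mouse.

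Ranked in the same way, several genes had 2 entering probes in the same direction. Rgs2, a regulator of G protein signalling, was 1.29 higher with probes at 1.29 and 1.30 and a dimmer probe at 0.67, and Cspp1 was 1.12 higher with both probes at 1.12. The exchange factor gene Kalrn (1.06), Tmc6 (1.01) and Pwp2 (0.93) followed. The lower side held Atg7, an enzyme of autophagosome formation (-0.98), the muscle-type phosphofructokinase Pfkm (-0.97), Cul1, the scaffold of SCF ubiquitin ligases (-1.04), Gpd1l (-1.19) and the RNA-binding protein gene Rbm6 (-0.92). Dimmer probes of Cul1 were at 0.05 and 0.12, and with them the gene was at -0.45. A Gpd1l probe, at -1.61, stood apart in the 174-day mouse only, and the other was at -0.78. Rgs2 and Cspp1 were the 2 genes with every entering probe at least 2-fold apart.

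No gene list stood apart in the diet comparison. The insulin-like growth factor axis had a median of -0.60 over 5 genes (4.12th percentile), with the binding protein Igfbp3 at -1.19, Igf2 at -0.72 and Cish, a target of growth hormone signalling, at -0.60, while Igfbp4 was at 1.00 and Igf1 at 0.17. A dimmer Igf2 probe was at 0.24, and Igf2 was at -0.24 with it and at -0.17 after the correction for position. Igf1 was at 0.03 without the brightness filter and at -0.34 after that correction. With each array centred on its median alone, this list lay at the 2.01st percentile. Proteasome genes had a median of -0.26 over 24 genes (5.43rd percentile), of which 17 were below 0, among them Psmb4 (-0.96), Psmc5 (-0.69) and Psmd2 (-0.65). The proteasome list was made from gene symbols and holds genes that encode no subunit, among them Psmc3ip, Psme3ip1, Psmg2, Psmg3 and Psmg4. The lists of translation factors, oxidative phosphorylation, cytoskeleton, ribosomal proteins, conjugation enzymes, cytochrome P450, histone and histocompatibility genes were made from gene symbols too. Eif2ak1, Eif2ak4 and Eef2k came into the translation factors that way, and Ndufaf1, Ndufaf6 and Sdhaf2 into oxidative phosphorylation. Tubgcp2, Tubgcp5 and Tubb2a-ps2 came into the cytoskeleton list. Cytoskeleton genes had a median of -0.28 over 17 genes (5.45th percentile) and lay at the 2.35th percentile after loess, at the 1.62nd without the brightness filter and at the 0.905th among the top 25% of probes by level. Fasting-related genes of gluconeogenesis had a median of 0.16 over 6 genes (74.1st percentile), with Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, at 1.31. Fatty acid oxidation and ketogenesis genes had a median of -0.004 over 14 genes (59.2nd percentile). Fatty acid synthesis genes had a median of -0.002, although Acly alone was at -1.41. Antioxidant enzyme genes had a median of -0.16 over 15 genes (25.5th percentile), with Hmox1 at -1.02 and the mitochondrial superoxide dismutase Sod2 at 1.01. The 6 hepatocyte genes had a median of 0.13 (81.8th percentile), and without the brightness filter 8 such genes lay at the 99.7th percentile. Hspa5 was at -0.33, with entering probes at -0.68 and 0.01 and a dimmer probe at -0.05. H19 was at 0.01, with entering probes from -0.05 to 0.34.

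The diet counts depended on spot position and on the scaling. After the correction for spot position, 75 of the 265 genes stayed at least 2-fold apart in the same direction. Rnmt (1.86), Esyt1 (1.57) and Gpd1l (-1.32) were among them, although Rnmt was at 0.90 without the brightness filter, Esyt1 at 0.92 with median centring and Gpd1l at -0.78 without the spots apart only in the 174-day mouse. After the correction Xbp1 (0.89), Cyp2s1 (0.98), Oxsm (0.88), Xpnpep1 (0.93), Cdkn1c (0.83), Rgs2 (0.85), Cspp1 (0.62), Kalrn (0.52), Tmc6 (0.70) and Alb (0.53) were below 2-fold, and Atg7 (-0.35), Rbm6 (-0.26) and Pfkm (-0.56) lay closer to 0. In the age comparison 29 of 45 genes stayed, while Atp6v0a1 (-0.64) and Cited4 (-0.76) did not. The share of lower genes was 67.2% with quantile normalization and 92.5% with median centring in the diet comparison, and 37.8% and 18.7% in the age comparison.

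Both older mice were then set against the same 17-day mouse. Hsbp1, Map1lc3b, H3f3b, Cyhr1, Gstp1 and Csf1, a growth factor of macrophages, were at least 2-fold lower in both, and no gene was at least 2-fold higher in both or apart in opposite directions. In the calorie-restricted mouse these genes were at -4.53 for Hsbp1, -1.97 for Map1lc3b, -2.19 for H3f3b, -1.62 for Cyhr1, -1.76 for Gstp1 and -1.45 for Csf1, which was at -1.11 in the ad libitum mouse. The Hsbp1 spot read 2769 in the 17-day mouse, 11.7 in the 174-day mouse and 139.3 in the calorie-restricted mouse. Of the 6 genes, 3 rested on a spot that stood apart in the 17-day mouse only, those of Hsbp1, Map1lc3b and H3f3b, and without such spots 3 genes were at least 2-fold lower in both. Each of the 6 except H3f3b had 1 entering probe. The dimmer probes of Cyhr1 were at 0.37 and 0.18 in the calorie-restricted mouse and that of Map1lc3b at 0.28. The other 3 probes of H3f3b lay from -0.74 to 0.50 there, and without the brightness filter H3f3b was at -0.55, Map1lc3b at -0.84 and Cyhr1 at 0.18. Independent lists would share 0.189 lower and 0.130 higher genes, and simulated mice with probe spread alone, set against a shared young mouse, gave a mean of 0.43 lower (0 to 3) and 0.35 higher (0 to 2). The simulated spread was normal, with an SD of 0.10 log2 for the 17-day mouse, so a spot as far apart as that of Hsbp1 hardly arises in it. Part of the excess may come from the shared 17-day arrays, which a single mouse did not allow to be split. Against the 17-day mouse, 18 genes were at least 2-fold higher and 43 lower in the calorie-restricted mouse. The share of lower genes was 70.5%, and 83.3% after loess. No list stood apart, the nearest being the insulin-like growth factor axis with a median of -0.45 over 5 genes (3.92nd percentile).

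Across genes, which are not independent replicates, the differences of the 2 older mice from the young mouse correlated with a Pearson r of 0.009, against a simulated mean of 0.059 (0.02 to 0.10), with a covariance of 0.0016 against 0.0097 (0.0028 to 0.0164). Both observed values lay below every simulated run. All runs, here and in the next comparison, held the estimated probe spread of each mouse fixed (0.10 log2 for the 17-day mouse). The error of these estimates was not carried into the runs, so a value outside them decides nothing. The age and the diet difference, which share the 174-day mouse with opposite sign, correlated at -0.70 against a simulated -0.73 (-0.75 to -0.71), closer to 0 than every run, with a covariance of -0.172 against -0.175 (-0.188 to -0.162). Rsl1d1, Arhgap1 and Mrpl50 lay at the ends of that relation.

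**Figure D3:**
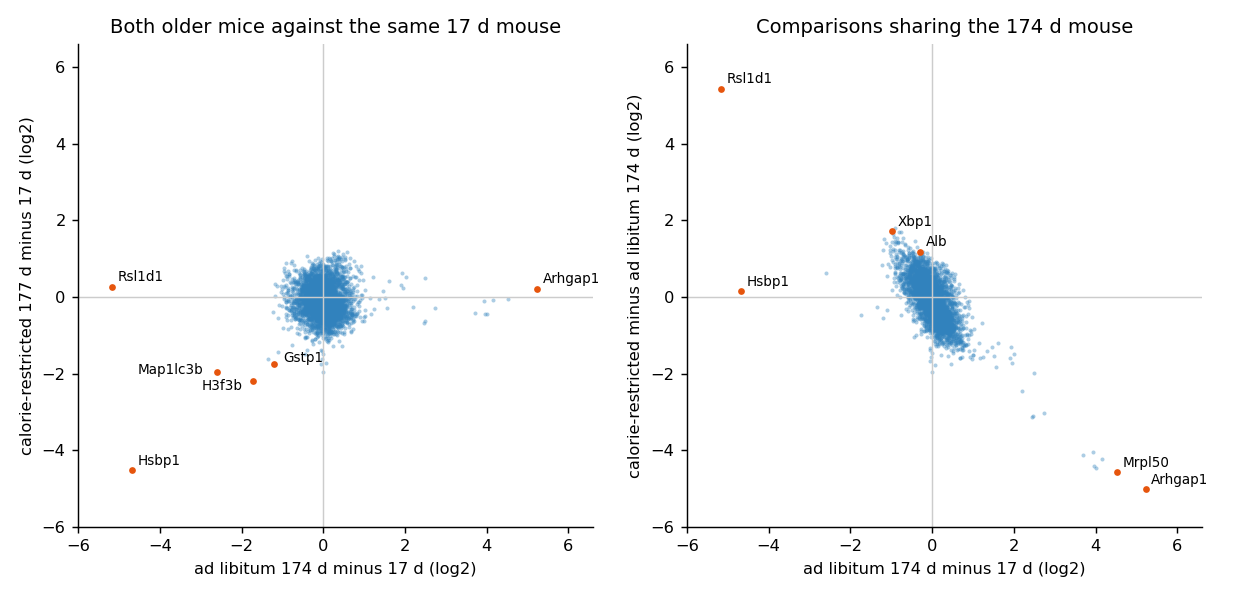
Log2 differences of 3865 genes (points) between mice, with selected genes in orange. On the left, the calorie-restricted mouse minus the 17-day mouse is plotted against the ad libitum 174-day mouse minus the 17-day mouse, and Hsbp1, Map1lc3b, H3f3b and Gstp1 lie low on both axes (r = 0.009 over all genes). On the right, calorie-restricted minus ad libitum is plotted against 174 d minus 17 d, and the shared 174-day mouse gives a falling relation (r = -0.70).

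Probes of a gene gave the only measure of technical spread. Over 263 genes with probes on both arrays, array A and array B correlated at an r of 0.081 (Spearman 0.123) in the age comparison and 0.115 (0.126) in the diet comparison. The pooled SD of probe differences around their gene mean was 0.45 log2 for age and 0.58 for diet, close to the SD over all genes of 0.42 and 0.59. All probes shared a direction in 50.1% of the 557 genes with at least 2 probes in the age comparison and in 49.7% in the diet comparison. Mice simulated with probe spread alone gave a mean of 85.4 genes at least 2-fold apart for age (60 to 107 in 100 runs) and 288.8 for diet (245 to 338), against the observed 45 and 265. In these 2 comparisons the numbers of 2-fold differences were no larger than in the simulated mice, and the age count lay below every run. The simulation drew normal spread at the pooled SD, which single spots far apart raise. The 2 probes of Mrpl50 alone had an SD of 6.25 for age and 6.08 for diet. Counts without such spots were not simulated. Between the calorie-restricted and the 17-day mouse 61 genes were at least 2-fold apart, above the simulated mean of 39.8 (25 to 58). A single probe stood for 41 of the 45 genes in the age comparison and 251 of the 265 in the diet comparison.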

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

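All tests here were chosen after the result was seen except, for the agreement of the arrays, those on level ranks across arrays, on bright probes and on hepatocyte against foreign tissue genes. Spots without a single gene name were not used in the comparisons, and 3924 of them passed the brightness filter. Of these, 47 were at least 2-fold apart in the age comparison (33 higher, 14 lower), 278 in the diet comparison (139 and 139), and 97 between the calorie-restricted and the 17-day mouse (49 and 48).

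On array A, 99 spots stood at least 1.5 log2 from both other mice in the ad libitum 174-day mouse alone, 82 brighter and 17 dimmer. The 17-day mouse had 7 such spots there and the calorie-restricted mouse 11. On array B the 174-day mouse had 30, against 4 and 8 in these mice. The checks here took the spots of array A. Those of Arhgap1, H2az1 and Lig1 were among the 8 highest with age and the 8 lowest with diet. A transcript difference in that mouse stays open: 24 other probes of these genes departed by a median of 0.0692 log2 (bootstrap interval -0.0608 to 0.258) where the spots departed by 1.95, but probes of a gene hardly agreed anywhere, so this decides nothing. Low brightness of that array stays open too. Such spots made up 0.26% of the brighter and 2.08% of the dimmer spots, a ratio of 0.125. Brighter and dimmer were set by the other 2 mice, and 82 of the 99 spots were picked as brighter than in those mice. That choice can itself favour spots dim in the other mice, so the ratio decides nothing. A defect at a place on the array stays open, since 9.09% of these spots had another within 2 spot numbers, against 4.04% in random draws (0 to 10.1%).

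Arrays A and B hardly agreed on the differences of the same genes. Probes named for the wrong gene are a candidate explanation, since level ranks of 963 genes with probes on both arrays had a Spearman correlation of only 0.0239, and at 0.121 among the 263 with entering probes, although spot brightness also depends on the clone. A shift of all names against the spots of array A is argued against by the hepatocyte probes. Their median level rank of 0.821 lay at the 99.58th percentile of random probe sets. Alb, Apoa1, Serpina1e and Ttr were among the brightest, but Nr5a2 ranked at 0.674, Itih1 at 0.474 and Apob at 0.428. That check covered array A only. On array B the ribosomal protein probes came highest of the lists ranked there, at the 96.2nd percentile. Noise of dim probes stays open, because among 64 genes in the top 25% by level the higher r was 0.0333 (interval -0.214 to 0.277). Signal not set by transcript level stays open too, since hepatocyte genes exceeded foreign tissue genes by 0.352 in median rank with an interval of -0.0408 to 0.516 (8 and 7 genes).

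Xbp1, Cyp2s1, Cdkn1c and Rgs2 were among 265 genes at least 2-fold apart in the diet comparison. Position on the array may account for many of these, since 75 stayed 2-fold apart in the same direction after the correction for position, against 192 to 211 after the same correction at shuffled positions (20 shuffles). The block length was picked on these same differences. Picked anew in each of 20 shuffles it left 113 to 237 genes, and picked on either array kind alone it was 528 spots. Spread between probes with no difference between genes may also account for the count, since 265 lay within the 245 to 338 of simulations with probe spread alone. That spread is raised by single spots such as the array A spot of Mrpl50 (SD of its probes 6.08), and the spread between misnamed probes would hold gene differences too. In the age comparison the same simulation gave 60 to 107 genes, more than the 45 observed. A difference between the diets, or between these 2 animals, was not tested and stays open with 1 mouse per group.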

How the results depend on the processing

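The correction for spot position and the 3 settings that leave out spots were chosen after the data were seen. No paired analysis was possible because each group held 1 mouse and no result came from a test, and for the same reason no replicate could be left out. In the age comparison, the 28 higher and 17 lower genes became 9 and 5 on array B alone, 140 and 90 without the brightness filter, 143 and 190 at 1.5-fold, 5 and 5 among the top 25% of probes by level, and 5 and 3857 without scaling. Higher genes became 61 with median centring and 12 without the spots apart only in the 174-day mouse, and lower genes 8 after the correction for position. In the diet comparison, the 87 higher and 178 lower genes became 49 and 105 on array A alone, 50 and 94 on array B alone, 50 and 613 with median centring, 219 and 313 without the filter, 36 and 79 after the correction for position, 445 and 658 at 1.5-fold, 28 and 56 in the top 25%, and 3827 and 6 without scaling. For the calorie-restricted against the 17-day mouse, the 18 higher and 43 lower genes became 3 and 8 on array B alone, 212 and 383 at 1.5-fold and 9 and 26 in the top 25%. Higher genes became 7 after loess and 4 after the correction for position, and lower genes 120 without scaling. A lower threshold, fewer probes or 1 array change the number of genes by construction, and without scaling the dimmer 174-day arrays set the direction, lower genes making up 99.9% in the age and 0.157% in the diet comparison. Between the calorie-restricted and the 17-day mouse, without a 174-day array, they made up 87.0%. The 6 genes lower in both older mice became 2 on array B alone, 10 without the filter, 20 at 1.5-fold, 3 in the top 25%, 120 without scaling and 3 without the spots apart only in the 17-day mouse. The 0 genes higher in both became 1 each with the brightest probe, the floor at the 25th percentile, no filter and without the spots apart only in the 174-day mouse, and 12 at 1.5-fold. Median centring moved the median of all genes by 0.24 log2 in the age and -0.27 in the diet comparison. Against that shift the antioxidant median of 0.4155 and the hepatocyte median of 0.2094, which changed sign, stood at the 94.1st and 4.92nd percentiles in the age comparison. The antioxidant median was -0.0538 on array A alone, 0.185 on array B alone (94.1st percentile), 0.0921 after the correction for position and 0.0107 in the top 25%, and none of these stood apart. The hepatocyte median was -0.177 after the correction for position, and array B measured none of these genes. Lists apart in the age comparison numbered 2 in the main setting, 0 on array B alone, 3 each with the brightest probe and without the filter, 1 in the top 25% (hepatocyte genes) and 1 with median centring, which was cytoskeleton (2.19th percentile). After the correction for position they were 2 other lists, cell cycle and fatty acid synthesis. In the diet comparison 0 lists stood apart in the main setting, 1 each after loess, with median centring and in the top 25%, and 2 without the filter. The r between arrays A and B became 0.015 for age and 0.029 for diet without the filter, and 0.017 for diet after the correction for position. Of 352 values of named genes under alternatives in the age comparison, 327 moved by less than the probe spread, 25 by more and 0 values at least 2-fold apart changed sign. Of 291 in the diet comparison, 266 moved by less, 23 by more and 2 values at least 2-fold apart changed sign, Alb to -0.148 with median centring and Xpnpep1 to -2.114 without the filter, which let in a 2nd spot that stood apart only in the 174-day mouse. Many values in both tallies could not move, such as that of Arhgap1, measured on array A only, under array A alone. A setting that removed the only spot of a gene gave no value, so such losses were not counted. The tallies are therefore no measure of stability. Smaller values also changed sign, those of Alb, H19, Hspa5, Igf1, Igf2 and Serpina1e with age and of H19, Hspa5 and Igf1 with diet. The cause of the other changes was not tested. Brightness limits the 174-day mouse most, with 1020 spots of array A below 10 against 28 and 26 in the other mice.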

Other observations

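Besides the erythroid list, 2 lists of non-hepatocyte cell markers held enough genes for a percentile, and none of the 3 stood apart in either comparison. Erythroid genes had a median of 0.17 over 8 genes in the diet comparison (83.4th percentile). Kupffer cell and macrophage genes had a median of -0.19 over 5 genes in the age comparison (15.5th percentile), and 0.05 in the diet comparison (60.9th). With age the lysozyme gene Lyz2 was at -0.29 and the complement gene C1qc at -0.21, but Cybb at 0.17. Stellate cell and fibroblast genes had a median of -0.10 over 13 genes with age, 10 of them below 0 (23rd percentile), and 0.11 with diet (82.3rd). Acute phase genes had medians of -0.10 and 0.20 over 5 genes (34.1st and 81.1st percentiles). With too few genes for a percentile, endothelial markers had a median of 0.05 with age and -0.18 with diet over 3 genes, bile duct markers 0.28 and -0.18 over 4, and neutrophil markers -0.02 and 0.43 over 2. Muscle markers were at 0.23 with diet over 3 genes. The lists for B cells and female-biased genes each had 2 genes with a probe, none of which passed the brightness filter, and those for T cells and adipose tissue had no named probe.

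Housekeeping groups also stayed within the range of random lists. The 47 ribosomal protein genes had a median of 0.02 with age (78.6th percentile) and -0.14 with diet (14.5th), and Rpl29 was at 1.55 and -1.83. Oxidative phosphorylation genes had medians of 0.03 and -0.12 over 36 genes (82.4th and 19.9th percentiles), with Atp5e at 0.87 and -1.23. Translation factors were at 0.005 and -0.03 over 29 genes, and chaperones at -0.03 and 0.02 over 23. Genes of amino acid breakdown and the urea cycle had a median of 0.13 with age over 13 genes (93.1st percentile), with Ahcy, which hydrolyses S-adenosylhomocysteine, at 1.22, the glutamate dehydrogenase Glud1 at 0.58 and the glycine decarboxylase Gldc at -0.80. Conjugation enzyme genes were below 0 for all 5 genes with age, at a median of -0.07 (38.3rd percentile). Among groups with too few genes for a percentile, apolipoprotein and lipid transport genes had a median of 0.23 with age and -0.41 with diet over 4 genes, with the HDL receptor Scarb1 at 0.39 and -0.61 and the cholesterol exporter Abca1 at 0.39 and -0.60. The 3 male-biased genes, Cyp7b1, Gstp1 and Nudt7, had a median of -0.49 with age and -0.11 with diet. Cytochrome P450 genes were at -0.51 and 0.55 over 3 genes, bile acid genes at -0.45 and 0.15 over 3, complement and coagulation genes at -0.10 and -0.22 over 3, and histocompatibility genes at -0.02 and -0.15 over 4. Histone genes, at 0.51 and -0.89, comprised H2aj, H2az1 and H3f3b. With age, cytoskeleton genes had a median of -0.002 over 17 genes (65.9th percentile) and proteasome genes 0.07 over 24 (90.3rd percentile).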
